A study of Mus musculus with 9 samples.

How the data were processed

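Gene expression was measured by RNA sequencing in EHE17 cells, a mouse endothelial tumour line, in 3 groups of 3 biological replicates: vehicle (DMSO), MGH-CP1 at 10 µM and dinaciclib at 300 nM, both compounds for 16 h. Per the labels' protocols, messenger RNA was captured from total RNA on poly-T beads, fragmented and copied with random primers, and the second strand was made with dTTP, so the libraries carry no strand mark. Samples were placed in groups by their labels.

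Per the submitters' processing notes, the tools were fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0. The genome build and annotation are not given in the sources used here. Coordinates were taken as GRCm38 because all 471 and all 251 gene identifiers of the tables are in GENCODE M21, with the same start and end for 464 (98.5%) and 242 (96.4%) of them. Older histone symbols were matched through the synonyms of a RefSeq gene table of the same assembly (GRCm38.p6).

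The data are 2 gene tables, each setting 1 compound against the same 3 vehicle libraries. Per the file headers, each holds the authors' raw read counts per gene and library as whole numbers. A further set of columns holds the authors' normalised signal, which on the values is the count divided by 1 size factor per library, and the authors' group means of it. FPKM columns were deposited too, per the file headers, and they give each library's total count exactly from count, FPKM and gene length. The deposited log2 fold changes, p-values and adjusted p-values are the authors' own comparison, and the gene lengths are the authors' as well. All listed genes have a deposited adjusted p below 0.05 and an absolute log2 fold change of at least 1. The dinaciclib table lists only genes with an entry in a column of tumour types, and 250 of its 251 genes are protein-coding. Levels of other genes were not analysed here.

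The total counts were 31852117, 34153170 and 40020833 for vehicle, 24310817, 19934012 and 23679849 for MGH-CP1, and 2541162, 3316779 and 2861512 for dinaciclib. Size factors and totals were recovered by division, and 100% of values gave the same factor and total within rounding. No replicate pair was closer than sampling noise: the chi-square of their counts was 5.92 to 239 times its degrees of freedom. Bounds for genes with 0 counts use a floor of 3 counts over the group and cover counting error only.

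Each comparison was fitted with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood test (two-sided) on the deposited counts, with no covariate and only the 6 libraries of the table. Genes were kept by filterByExpr with a minimum count of 10. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. The test planned TMM factors, which assume that most genes in the table are unchanged. The tables hold only genes picked for change, so the authors' size factors set the library scale and TMM became an alternative. The dispersion was estimated on the same picked genes, and since the authors had picked them on these libraries, a call here is no independent evidence and the adjusted p is no error rate over the genome.

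On simulated counts with the real means and depths, the test called 2.03% of unchanged genes, 78.2% of genes changed by a log2 of 1 and 100% of those changed by a log2 of 2 among 356 MGH-CP1 genes. For 248 dinaciclib genes these shares were 6%, 97% and 100%. The unchanged genes numbered 197 and 50. Rises and falls were drawn at random, with the dispersion trend of the listed genes. The real tables hold only genes picked for change, so these shares are not error rates for them.

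In 31 lists, 937 genes were fixed before the data were examined, together with the tests and the rule for named genes. For lists with at least 5 tested members, Fisher's exact test (two-sided, scipy 1.17.1) set higher against lower calls in the list beside the other called genes, adjusted over the lists; it treats genes as independent. The genes named are the 8 largest rises and 8 largest falls per comparison among called genes with a mean at or above the table's median, separate replicate ranges and a regular symbol, up to 4 members of each list by smallest p, and 22 genes of TEAD, CDK and fusion biology wherever listed. Genes in both tables were also compared in a single fit over the 9 libraries.

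Alternatives were TMM factors over the listed genes, total counts as library sizes, DESeq2 1.42.0, no count filter, a stricter threshold, a minimum fold, the table's upper part by mean, the replicate number as a block, protein-coding genes alone, vehicle counts thinned to the dinaciclib depth, and leaving out each replicate in turn. Figures were drawn with matplotlib 3.10.9. Values of some listed genes are not reported here.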

Results

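EHE17 is a line of mouse endothelial tumour cells whose genotype is given as TC+/+ Cdkn2a −/−. Lines of this name come from mouse models of epithelioid hemangioendothelioma, a vascular tumour driven by fusion of TAZ (gene Wwtr1) with CAMTA1. The cells received DMSO vehicle, 10 µM MGH-CP1 or 300 nM dinaciclib for 16 h, with 3 biological replicates per group. MGH-CP1 blocks the palmitoylation of TEAD proteins, the DNA-binding partners of YAP and TAZ. Dinaciclib inhibits cyclin-dependent kinases, among them CDK9, which releases paused RNA polymerase II. The design asks which transcripts change with each compound.

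Vehicle libraries held 31852117 to 40020833 counts and MGH-CP1 libraries 19934012 to 24310817 counts. Dinaciclib libraries held 2541162 to 3316779 counts, so that the mean vehicle total was 12.2 times the dinaciclib total. The authors' deposited tables hold only genes picked for a change: 471 with MGH-CP1, of which 270 were higher and 201 lower, and 251 with dinaciclib, of which 65 were higher and 186 lower. A gene that is not in a table is not reported as unchanged. The listed genes took 1.05% to 1.95% of the counts in MGH-CP1 libraries and 0.522% to 0.708% in vehicle for the MGH-CP1 table, and 9.61% to 12.3% in dinaciclib libraries and 2.53% to 2.57% in vehicle for the dinaciclib table. Levels below are normalised counts, that is, counts divided by the authors' size factors, as mean ± SD over n = 3 libraries, and are relative to the rest of each library. They were normalised separately in the 2 tables.

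**Figure D1:**
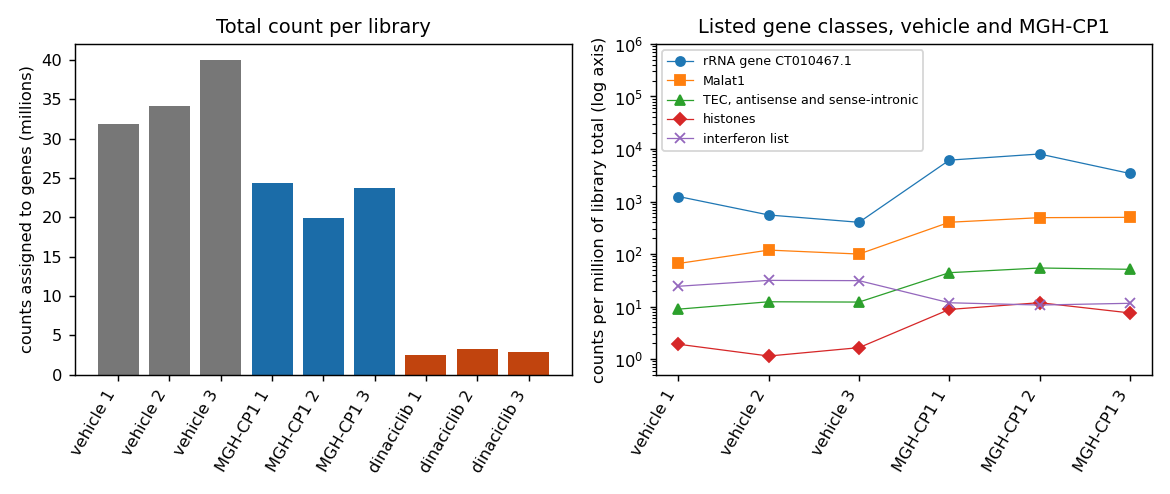
Left, total counts assigned to genes in each of the 9 libraries (unit 1e6 counts); right, levels as CPM of the library total on a log axis for 5 sets of listed genes in the 6 vehicle and MGH-CP1 libraries, each point 1 library. Dinaciclib libraries held 2541162 to 3316779 counts, and the rRNA gene CT010467.1 was higher in each MGH-CP1 library than in any vehicle library.

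With MGH-CP1, among called genes with a mean at or above the table's median, separate replicate ranges and a regular symbol, the 8 with the largest rises were mt-Ts2, Lilr4b, Hist1h1e, Rn7sk, mt-Th, Nptx1, Malat1 and Gdf15. The mitochondrial tRNA gene mt-Ts2 reached 88.3 ± 37.6 against 10.4 ± 1.88 in vehicle, and mt-Th 79.6 ± 37.7 against 12.2 ± 4.76. On the mitochondrial genome mt-Th (11546 to 11612) and mt-Ts2 (11613 to 11671) abut, so their rises may not be independent. Rn7sk, the 7SK RNA that holds the elongation kinase P-TEFb inactive, reached 85.1 ± 25.6 against 12.9 ± 11.2 (a log2 change of 2.73, or 3.63 without vehicle replicate 1), and the nuclear long non-coding RNA Malat1 13096 ± 1519 against 2660 ± 747. Among coding genes, Nptx1, a secreted neuronal pentraxin, rose 5.41-fold (715 ± 98.5 against 132 ± 18.3), the stress-induced cytokine gene Gdf15 rose 4.70-fold (146 ± 34.8 against 31.2 ± 13.1), and the leukocyte receptor gene Lilr4b rose 8.12-fold (82.2 ± 16.5 against 10.0 ± 2.20), with reads it may share with a near-copy. The rise of Nptx1 (ENSMUSG00000025582, chromosome 11, 119538719 to 119547753) was 2.44 on the log2 scale with SE 0.168, at an adjusted p of 1.85e-06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

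By the same limits the 8 largest falls were in AA465934, Tbxa2r, Ifit3, Phospho1, Ifit1, Kcnn3, Nckap1l and Col15a1. Tbxa2r, the thromboxane A2 receptor, stood at 15.6 ± 6.61 against 76.0 ± 7.12 in vehicle. The phosphatase gene Phospho1 stood at 35.4 ± 3.77 against 153 ± 26.6, the calcium-activated potassium channel gene Kcnn3 at 25.3 ± 6.38 against 107 ± 28.1, and Nckap1l, which encodes a haematopoietic subunit of the actin-regulating WAVE complex, at 108 ± 13.5 against 426 ± 32.8. Col15a1, a basement membrane collagen gene (ENSMUSG00000028339, chromosome 4, 47208161 to 47313167), fell by 1.97 on the log2 scale with SE 0.179, from 239 ± 37.8 to 60.6 ± 4.79, at an adjusted p of 9.20e-06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. AA465934 fell by 2.83 on the log2 scale with SE 0.931, but its vehicle mean of 47.8 ± 58.1 rests on replicate 2: without it the log2 change was −1.11 at an adjusted p of 0.0736 by the same edgeR test and adjustment.

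The interferon-stimulated genes of the fixed list were lower where they were in the table and tested, and such genes outside the list were not examined as a set. Of the 40 genes on the interferon list, 11 were in the table, 10 had enough counts to test, and 10 fell while 0 rose: Ifit1, Ifit3, Ifit3b, Isg15, Rsad2, Oas1a, Oasl2, Usp18, Rtp4 and Iigp1. Ifit3 stood at 9.49 ± 7.66 against 46.8 ± 3.24 in vehicle, Ifit1 at 12.7 ± 4.43 against 53.8 ± 14.2, Rsad2 (viperin) at 41.4 ± 8.37 against 111 ± 13.9, and the ubiquitin-like modifier gene Isg15 at 72.3 ± 9.19 against 175 ± 39.7. The median log2 change of the 10 was −1.34; that of Ifit3 was −2.24, or −2.88 without MGH-CP1 replicate 3. Among the other called genes 175 were higher and 170 lower, which gave an adjusted p of 0.00346 over the lists tested by Fisher's exact test on the calls of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Adjusted over the list alone, 10 members passed, which adds no support because every tested gene in the table passed. Ifit3 and Ifit3b are close copies on chromosome 19 (34583531 to 34588731 and 34607970 to 34613401) and may share reads.

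Replication-dependent histone genes, whose messages mostly lack poly(A) tails, were higher where listed and tested. Of 56 on the list, 12 were in the table, 6 could be tested, and 6 rose while 0 fell, with a median log2 change of 2.13. The linker histone genes Hist1h1e and Hist1h1d reached 67.3 ± 32.6 against 9.47 ± 3.31 and 57.4 ± 11.8 against 13.6 ± 9.54 (for Hist1h1d a log2 change of 2.03, or 2.80 without vehicle replicate 3), and the H4 gene Hist1h4k 18.1 ± 2.67 against 5.77 ± 0.495. Fisher's exact test on the calls of edgeR's quasi-likelihood test gave a Benjamini-Hochberg adjusted p of 0.0137. Adjusted over the list alone 6 passed, as every tested gene in the table did. Many histone genes have near-identical copies, mostly clustered on chromosome 13, so that the share of such genes is uncertain. The rRNA gene CT010467.1 moved the same way, at 0.586% ± 0.232 of all counts against 0.0734% ± 0.0449 (SD, n = 3), although the libraries were selected for poly(A).

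Of the fixed list of ATF4, CHOP and unfolded protein genes, 4 of 34 were in the table, and 4 rose and 0 fell. They were Aldh1l2 and Mthfd2 of mitochondrial folate metabolism, the cystine transporter gene Slc7a11, and Cth, which makes cysteine from cystathionine. Mthfd2 stood at 1243 ± 172 against 539 ± 110 and Slc7a11 at 901 ± 292 against 340 ± 60.04. All 4 passed when adjusted over the list alone, but so did every tested gene in the table, which adds no support. With under 5 members no list test was made.

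**Figure D2:**
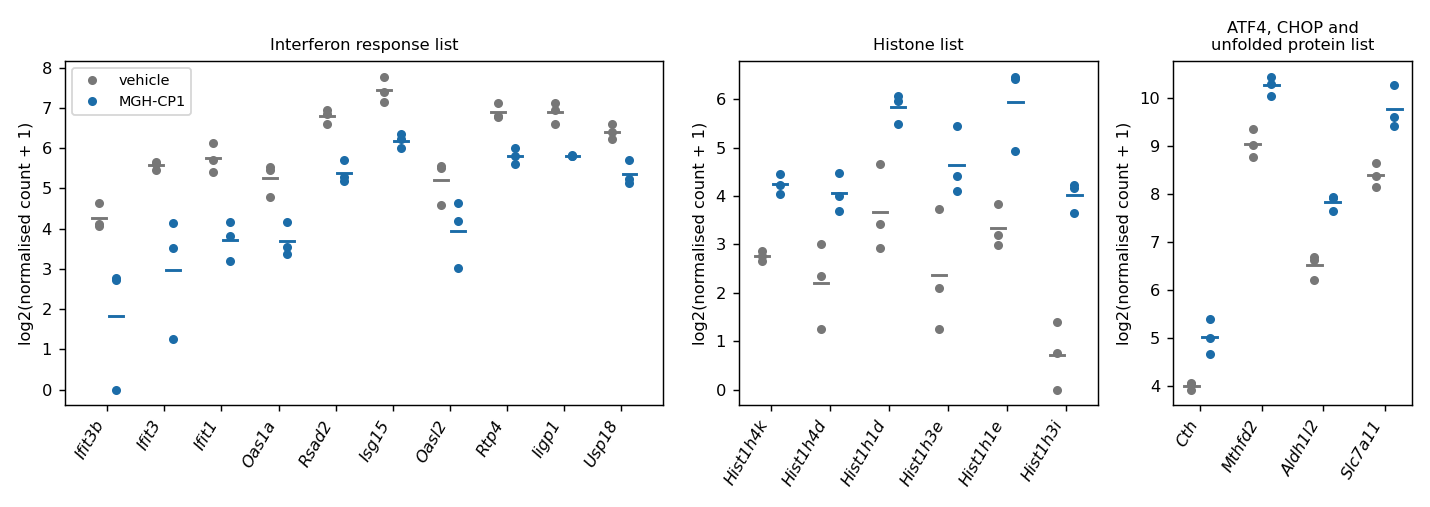
Normalised counts as log2(count + 1) for the tested members of 3 fixed lists; each point is 1 library, grey for vehicle and blue for MGH-CP1, and each bar the mean of 3 log values. The 10 interferon genes had lower means with MGH-CP1, and the 6 histone genes and 4 genes of the ATF4 list higher ones.

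Of the 32 targets of YAP, TAZ and TEAD on the list, 1 was in the table: Ccdc80, a matrix protein gene, was lower at 45.7 ± 8.13 against 121 ± 3.81. None of the 22 genes always looked for, among them Ccn1, Ccn2, Ankrd1 and the TEAD genes, was in the MGH-CP1 table. Of vascular genes, the growth factor gene Vegfa rose (321 ± 24.3 against 138 ± 28.2), while the von Willebrand factor gene Vwf fell (20.5 ± 9.20 against 66.9 ± 9.07) and the TIE2 ligand gene Angpt1 fell (6.12 ± 4.65 against 18.6 ± 2.45, a log2 change of −1.65, or −2.37 without MGH-CP1 replicate 2). Of immune cell markers, the macrophage gene Cd68 rose (54.8 ± 17.6 against 12.2 ± 5.08) and the lysozyme gene Lyz2 fell (92.8 ± 25.7 against 187 ± 16.9). No marker of fibroblasts, mural cells or epithelium was in the table, and neither were members of the lists for the Hippo core, cell cycle phases, cyclins, cholesterol, heat shock, recombination, RNA polymerase II, chromatin, receptor kinase feedback, or Notch and Wnt.

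Lists with 1 or 2 members in the table gave single values. The early response gene Gadd45b (48.8 ± 8.28 against 24.3 ± 3.68), the TGF-beta binding protein gene Ltbp2 (32.3 ± 9.50 against 13.4 ± 3.40) and the mitochondrial rRNA gene mt-Rnr1 (5803 ± 1856 against 2336 ± 255) were higher. The chemokine gene Cx3cl1 (217 ± 20.4 against 578 ± 46.7), the stress-induced mTORC1 inhibitor gene Ddit4 (417 ± 75.6 against 947 ± 14.1), the pro-apoptotic gene Bik (187 ± 43.1 against 439 ± 45.4) and the complex I gene Ndufa1 (324 ± 64.6 against 670 ± 59.1) were lower. The ribosomal protein genes Rps27a (2588 ± 283 against 6095 ± 2436) and Rpl24 (10.6 ± 4.80 against 30.2 ± 12.6) were lower too, with reads that can fall on their many pseudogenes.

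In all, 355 of the 471 genes had enough counts to test by edgeR's quasi-likelihood test, and 355 passed Benjamini-Hochberg adjustment, 175 higher and 180 lower. The genes had been picked by the authors on these same libraries. With protein-coding genes alone, 187 passed, 86 higher and 101 lower.

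With dinaciclib, 186 of the listed cancer-annotated genes were lower and 62 higher by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, over 248 tested. Among called genes within the same limits, the steepest falls were in Ralgds, an exchange factor for Ral GTPases (19.5 ± 14.2 against 1227 ± 48.3 in vehicle), the nuclear pore gene Nup98 (32.2 ± 17.99 against 776 ± 27.2) and the P-body RNA helicase gene Ddx6 (119 ± 38.9 against 2880 ± 129). Cant1, a calcium-activated nucleotidase gene, stood at 43.4 ± 3.08 against 786 ± 10.0, the acetyltransferase gene Kat6a at 66.2 ± 22.2 against 939 ± 56.9, the splicing factor gene Srsf3 at 147 ± 27.7 against 2085 ± 104, the histone chaperone gene Set at 202 ± 117 against 2676 ± 87.5, and Nfe2l2, which encodes the oxidative stress regulator NRF2, at 138 ± 33.9 against 1752 ± 55.1. For Ralgds (ENSMUSG00000026821, chromosome 2, 28513125 to 28553081) the log2 change was −5.97 with SE 0.357 and an adjusted p of 6.76e-07 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, on 18 counts in the 3 dinaciclib libraries.

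The 8 largest rises within these limits were in Fstl3, Cox6c, Tfrc, Calr, Hmga1b, Ext2, Aldh2 and Rpn1. Fstl3, which encodes an activin-binding protein, reached 2109 ± 415 against 56.7 ± 3.66, and the transferrin receptor gene Tfrc 8488 ± 924 against 247 ± 27.9. The endoplasmic reticulum chaperone gene Calr reached 197482 ± 31035 against 6952 ± 112, the oligosaccharyltransferase gene Rpn1 37086 ± 5138 against 2080 ± 41.8, the heparan sulfate polymerase gene Ext2 38054 ± 5418 against 1755 ± 34.5, and the mitochondrial aldehyde dehydrogenase gene Aldh2 49224 ± 6284 against 2394 ± 69.6. Hmga1b, of a family of architectural chromatin proteins, reached 5251 ± 699 against 208 ± 4.21, with reads it may share with its near-copy Hmga1. For Tfrc (chromosome 16, 32608920 to 32632794) the log2 change was 5.10 with SE 0.131 and an adjusted p of 1.55e-08 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

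The labels do not spell out TC in the genotype, which is read here from general knowledge as the TAZ-CAMTA1 fusion allele; the genes of both partners were in the dinaciclib table. Camta1 (chromosome 4, 150917322 to 151861876) stood at 453 ± 89.4 against 2550 ± 22.6 in vehicle, and Wwtr1 (chromosome 3, 57455649 to 57575910) at 135 ± 11.8 against 471 ± 22.7. Gene counts do not separate fusion from native transcripts. Nf2, the tumour suppressor gene upstream of the Hippo kinases, was higher, at 11108 ± 1676 against 1069 ± 14.8. With TMM factors over the listed genes Wwtr1 lost its call, at a log2 change of −0.18. These factors take most listed genes as unchanged and shift such a picked set by construction. Values under them, here and below, therefore do not test whether a single gene fell. With total counts as library sizes, which moved the median log2 change by only 0.13, that of Wwtr1 was −1.67.

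Cyclin and kinase genes went both ways. The G1 cyclin genes Ccnd1 (47960 ± 3870 against 7368 ± 618) and Ccnd3 (8225 ± 1261 against 1709 ± 70.2) and the kinase gene Cdk4 (6779 ± 729 against 3237 ± 93.5) were higher, while the kinase inhibitor gene Cdkn2c was lower. Of short-lived transcripts, Jun (8395 ± 725 against 1493 ± 68.5) and Hey1 (407 ± 39.6 against 37.2 ± 3.26) were higher and Klf6 lower (193 ± 118 against 1349 ± 23.1). Bcl6, a transcriptional repressor gene, had 0 counts in the 3 dinaciclib libraries and was at least 11.1-fold lower. The apoptosis inhibitor genes Bcl2 (115 ± 58.3 against 410 ± 40.2) and Birc3 (15.1 ± 13.4 against 81.1 ± 8.74) were lower. Without dinaciclib replicate 2 the log2 change of Klf6 was −3.39 in place of −2.78 and that of Birc3 −2.95 in place of −2.32. Of p53 targets, Ddb2 (203 ± 42.9 against 14.5 ± 2.84) and Mdm2 (1410 ± 370 against 493 ± 8.48) rose, while the death receptor gene Fas had 0 counts and was at least 2.68-fold lower.

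Endothelial genes in the table were lower: 5 of 5 tested fell, among them the VEGF receptor gene Kdr (1789 ± 222 against 8417 ± 280), Notch1 (577 ± 30.5 against 2857 ± 7.40), and the transcription factor genes Gata2 (52.9 ± 13.9 against 508 ± 27.3) and Fli1 (153 ± 111 against 1152 ± 20.996); with TMM factors 4 passed the threshold, all lower. Without dinaciclib replicate 2 the log2 change of Fli1 was −3.70 in place of −2.88. The growth factor receptor gene Fgfr1 (1281 ± 102 against 4555 ± 10.6) was lower, and the platelet-derived growth factor gene Pdgfb had 2 counts in the 3 dinaciclib libraries against 139 ± 8.56 normalised counts in vehicle. Chromatin modifier genes gave 9 lower and 1 higher of 10, with Smarcb1 (40.2 ± 9.74 against 642 ± 39.9), Kdm6a (28.0 ± 4.45 against 342 ± 6.90), Arid1a (96.3 ± 10.6 against 1113 ± 26.4) and Suz12 (71.5 ± 17.01 against 586 ± 14.2) lower and Kmt2c higher; with TMM factors 6 were lower and 2 higher, Pbrm1 having changed sign. Homologous recombination genes gave 5 lower and 1 higher of 6: Palb2 had 0 counts and was at least 12.2-fold lower, Nbn stood at 38.3 ± 7.57 against 203 ± 11.05, and Fanca was higher at 428 ± 153 against 115 ± 7.92, while with TMM factors Blm and Brca2 changed sign. Of Notch and Wnt genes 3 were lower and 2 higher.

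Genes of respiratory chain subunits were higher where listed, 3 of 3: Cox6c of cytochrome oxidase (26437 ± 2961 against 759 ± 24.6) and the succinate dehydrogenase genes Sdhc (3132 ± 144 against 899 ± 19.9) and Sdhd (1500 ± 25.8 against 614 ± 26.0). The ribosomal protein gene Rpl22 (10739 ± 1221 against 2390 ± 116) and the chaperone gene Hsp90aa1 (20146 ± 1860 against 4506 ± 166) were also higher. Of elongation and mediator genes, Aff1 (124 ± 63.7 against 588 ± 19.8), Aff4 (411 ± 166 against 1328 ± 29.0) and Ell (130 ± 59.9 against 432 ± 1.30) were lower and Med12 (968 ± 198 against 484 ± 17.98) higher. The related ETS factor genes Etv4 (4112 ± 321 against 1069 ± 34.7) and Etv5 (52.1 ± 16.2 against 497 ± 19.5) went opposite ways. The proliferation genes Blm and Bub1b were lower, at 42.1 ± 30.7 against 107 ± 6.44 and 229 ± 83.8 against 633 ± 15.6, but both changed sign with TMM factors. The log2 change of Blm was −1.27, or −2.13 without dinaciclib replicate 2, and it lost its call without vehicle replicate 1 or 3 (adjusted p 0.0532 and 0.0545, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The endoplasmic reticulum stress gene Herpud1 (29.5 ± 45.4 against 285 ± 7.23) and the NF-kappaB subunit gene Nfkb2 (140 ± 43.2 against 361 ± 2.14) were lower, the second again with a change of sign under TMM. The log2 change of Herpud1 was −3.28, with −6.45 without dinaciclib replicate 3 and −2.66 without replicate 2.

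**Figure D3:**
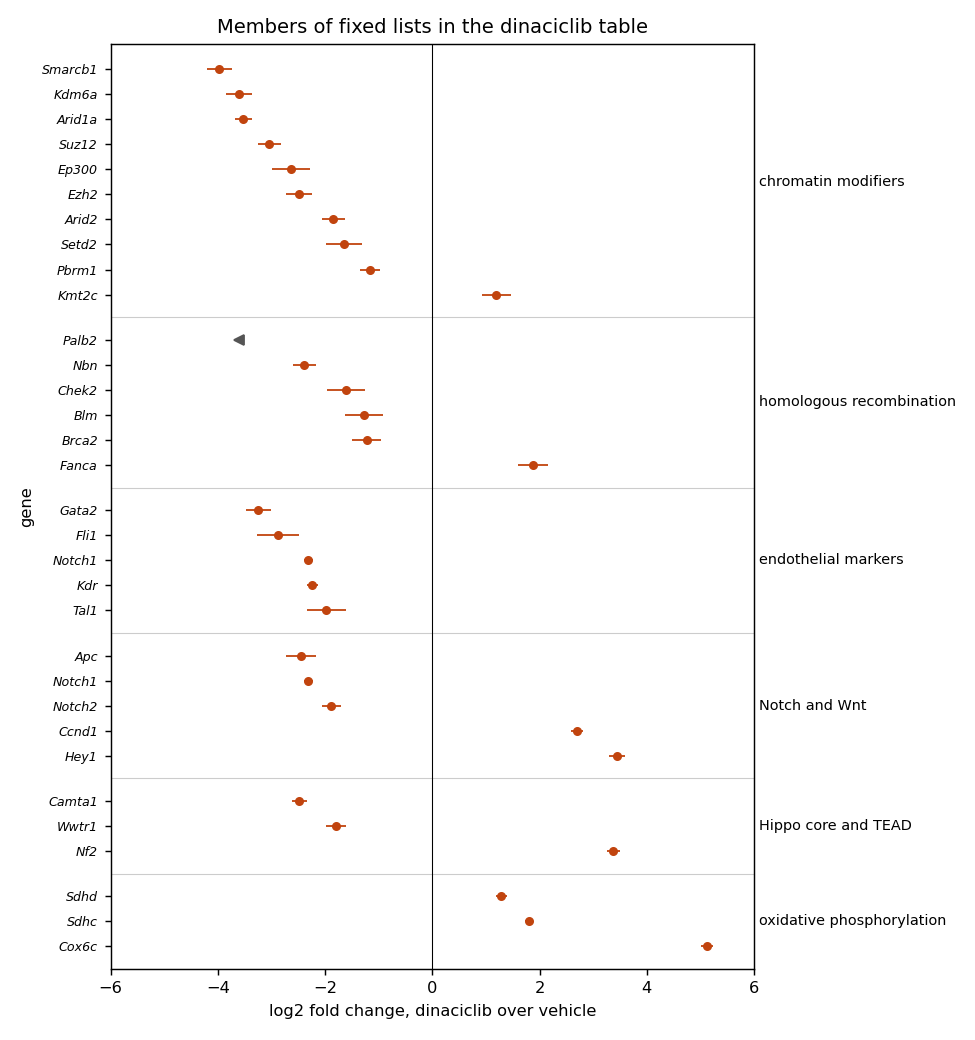
Log2 fold change of dinaciclib over vehicle (x axis) for listed members of 6 fixed lists (y axis), fitted over 3 and 3 libraries; points are fitted values, bars their SE, and the grey triangle is the bound for Palb2, which had 0 counts with dinaciclib. The 5 endothelial genes lie below 0 and the 3 respiratory chain genes above it.

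No list passed the test of its balance of higher and lower calls against the other called genes. Across 5 lists, Fisher's exact tests on the calls of edgeR's quasi-likelihood test gave Benjamini-Hochberg adjusted p-values of 0.507 for cyclins and kinases, 0.752 for endothelial, chromatin, and Notch and Wnt genes, and 1 for homologous recombination, with 0 lists below an unadjusted p of 0.05 and 0 by DESeq2. Of the other called genes, 74.4% to 75.7% were lower in these tests. All tested members of the lists passed when adjusted over the list alone: 5, 5, 10, 5 and 6. Every tested gene in the table passed as well, so this adds no support. Lists for histones, cholesterol, hypoxia, matrix, interferon, mitochondrially encoded genes, TGF-beta targets and other cell types had no member in the dinaciclib table. Because that table held only genes with a tumour type entry, this absence does not show how these sets responded.

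The balance of 75% lower calls was set beside other scales. TMM factors over the listed genes moved the median log2 change by 1.62 and gave 70 higher and 96 lower calls (57.8% lower), while total counts as library sizes gave 62 higher and 185 lower. Because TMM factors take most listed genes as unchanged, they shift such a picked set by construction and do not test its balance. With the TMM factors the calls of Aff1, Aff4, Ell, Bcl2, Birc3, Chek2, Fgfr1, Notch2 and Wwtr1 were lost. That of Fas was lost too, at an adjusted p of 0.0630 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Fas has 0 counts with dinaciclib, so its fitted log2 change of −6.96 against −7.04 before does not measure the size of its fall. The depth with dinaciclib, 2541162 to 3316779 counts, and the absence of an external standard here leave all its levels relative to the library.

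The tables had 2 genes in common out of 720 listed in either. The way the tables were made limits this overlap, which does not measure how alike the responses were. The dinaciclib table held only genes with a tumour type entry, 250 of 251 protein-coding. The MGH-CP1 table had no such column, and 211 of its 471 genes were protein-coding. Among them was Bcl11b, a zinc finger factor gene (chromosome 12, 107910403 to 108003602). It stood at 18.5 ± 5.99 against 48.9 ± 3.24 with MGH-CP1, and had 0 counts with dinaciclib, at least 5.56-fold lower. The adjusted p of its difference between compounds was 0.0287 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and it lay between 0.0527 and 0.0915 without MGH-CP1 replicate 2 or 3 or any of the dinaciclib replicates. That fit held only the 2 shared genes, with a common dispersion and adjustment over these 2. With 0 counts in the dinaciclib group the size of the difference cannot be estimated. The same vehicle libraries enter both comparisons, and simulated unchanged groups gave the same sign in 60.2% of 10000 draws for Bcl11b. These draws used a set dispersion of 0.05 and no picking for change. They show the pull of the shared vehicle and not how often genes listed in both tables would agree.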

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

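Total counts as library sizes, protein-coding genes alone and thinned vehicle counts were tried after the data were seen; the other alternatives were set beforehand. TMM factors over the listed genes moved the median log2 change by 0.13 with MGH-CP1, with 355 calls of the same direction, and by 1.62 with dinaciclib, where 42 genes changed sign and 166 passed. Among the named genes Blm 0.34, Bub1b 0.17 and Nfkb2 0.26 turned positive short of the threshold. The cause lies in the construction, since these factors take most listed genes as unchanged. With totals as library sizes the median moved by 0.13 with dinaciclib and 247 genes passed.

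Restricting to genes with a mean at or above the table's median left fewer to test: 236 MGH-CP1 genes, 126 dinaciclib genes (50 higher, 76 lower), 1 MGH-CP1 list and 0 genes shared by both tables. Protein-coding genes alone gave 187 MGH-CP1 calls. No count filter gave 471 and 251, as did DESeq2. At an adjusted p of 0.01 the difference between compounds had 0 calls where 1 passed before. Leaving out each replicate gave 365 to 386 MGH-CP1 calls, 240 to 249 dinaciclib calls, 2 to 2 and 0 to 0 lists, 1 to 2 shared genes and 0 to 1 differences. Bcl11b was under the count filter of the dinaciclib fit without any vehicle replicate, which gave the 1.

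Of the named genes, 1 with MGH-CP1 (AA465934) and 11 with dinaciclib lost their call under some alternative without a change of sign. Blm did so with the replicate block (adjusted p 0.0516), with thinning (0.0877) and without vehicle replicate 1 (0.0532) or 3 (0.0545), all by edgeR with Benjamini-Hochberg adjustment; its main value was 0.00626. The others did so with TMM factors: Aff1, Aff4, Bcl2, Birc3, Chek2, Ell, Fgfr1, Notch2 and Wwtr1, and Fas, which has 0 counts with dinaciclib.

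Groups share replicate numbers. Correlations of same-numbered libraries' deviations across genes were −0.013, −0.21 and 0.16 with MGH-CP1 and 0.16, 0.13 and 0.018 with dinaciclib, so not all were over the 0.1 set for pairing. Each dinaciclib library correlated best with its own number, a hint from the data and not the design, but vehicle replicate 3 did so with dinaciclib replicate 1 (0.046). With the replicate block 355 and 240 genes passed, with 2 and 0 lists, 2 shared genes and 1 difference. Tests meant for tables without counts (pseudocounts, rescaling, camera and fry) were not run, as counts were at hand and the genes were picked. Depth limits low counts with dinaciclib: a count of 3 in a library is a normalised 8.56 to 11.1 there and 0.773 to 0.974 in vehicle.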

Other observations

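The tests of gene types, of their positions by type and length, of transcription factor families and of thinned or total-count scaling were chosen after the values they use were seen. Beyond the fixed lists, the MGH-CP1 table held many genes that are poorly annotated or lie over other genes. In the authors' deposited table, higher levels were found for 56 of 60 TEC genes (a GENCODE class of models still awaiting experiments), 26 of 28 antisense genes and 7 of 7 sense-intronic genes. Of the 34 with enough counts, 28 were higher and 6 lower against 147 and 174 among the rest (Fisher's exact test, two-sided, p = 4.47e-05). Summed over the 89 higher ones, the level was 49.8 ± 5.18 CPM (of the library total) with MGH-CP1 and 11.1 ± 1.93 in vehicle (SD, n = 3). Processed pseudogenes leaned the other way, 33 higher and 59 lower against 142 and 121 among the rest (Fisher's exact test, two-sided, p = 0.00353), with reads that cannot be told from those of their parent genes by count alone. That rest includes the TEC, antisense and sense-intronic genes, which add to the gap. Protein-coding genes were also more often lower, 86 higher and 101 lower, and pseudogenes were not tested against them alone. Libraries without strand do not separate antisense genes from their partners.

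In the dinaciclib table, genes annotated with a transcription factor family were lower more often than the rest: 45 of 50 (90%) against 141 of 198 (71.2%), with an odds ratio of 3.64 and a two-sided Fisher p of 0.00571. The 5 that were higher were Jun, Hey1, Etv4, Foxo4 and Hmga1b. With TMM factors over the listed genes, 19 factor genes were called lower and 6 higher (76% lower) against 77 and 64 of the rest (54.6%; two-sided Fisher p = 0.0506). By rank, the log2 changes of the 50 and the 198 gave a two-sided Mann-Whitney p of 0.159.

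Among the genes the authors had picked as changed with MGH-CP1, those of 3 RNA classes that mostly lack poly(A) tails had higher summed levels; other genes of these classes were not analysed here. The rRNA gene CT010467.1 stood at 5864 ± 2319 CPM against 734 ± 449, the 12 listed histone genes at 9.40 ± 2.20 against 1.57 ± 0.393, and the 7 mitochondrial tRNA, 7SK and scaRNA genes at 26.9 ± 2.41 against 7.98 ± 0.978. A candidate explanation is more untailed RNA carried through selection, in which case these levels would follow the rRNA level among libraries of a group. Over the 6 libraries, with group means removed and 36 orders within groups, r was 0.667 for histones (one-sided exact permutation p = 0.111, adjusted 0.333, Spearman 0.543 with p = 0.222, r without the 2 farthest libraries 0.844) and 0.445 for the small RNAs (p = 0.222, adjusted 0.333, Spearman 0.429 with p = 0.222, r without the 2 farthest −0.396), with 3 relations computed. Too few libraries keep this open, and a response of histone or 7SK RNA to the compound stays open and untested beside it.

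The 89 higher TEC, antisense and sense-intronic genes may carry reads from introns of the coding genes around them. Of the 56 TEC genes, 87.5% lay mostly inside protein-coding genes against 59.5% of 3163 other annotated TEC genes (Fisher's exact test, two-sided, p = 6.95e-06, and Mantel-Haenszel p within bins of gene length 0.000142). Unspliced RNA would give this, but position was measured against whole gene bodies on either strand, exons included. Reads from exons of the coding genes could give the same excess, so introns are not singled out. The gap of 28.0 points argues against DNA spread evenly over such genes, although the background is not limited to genes that could have been detected. Reads from the coding genes and DNA both stay open as sources for the 26 antisense genes, at 84.6% against 68.2%, a gap of 16.4 points (Fisher p = 0.0897, Mantel-Haenszel p = 0.0393). Both also stay open for the 7 sense-intronic genes, at 100% against 96.3%, a gap of 3.75 points (Fisher p = 1) in a class defined by lying in introns. The summed level of the 89 had an r of −0.639 with the rRNA gene within groups (exact permutation p = 0.806 for a positive and 0.222 for a negative relation, adjusted 0.806, Spearman −0.600 with p = 0.778, r without the 2 farthest libraries −0.0676), which leaves untailed RNA open as a source. A change in transcription or splicing with the compound was not tested.

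More listed genes were lower than higher with dinaciclib. With vehicle counts thinned to the dinaciclib depth, 173 of 186 lower calls were kept (93.0%), so most of these calls do not rest on the deeper vehicle libraries. The genes had been picked at the real depths. Thinning therefore cannot show how depth shaped which genes were listed, and depth stays open as a cause of the balance. The scale stays open. Total counts as library sizes gave 74.9% lower calls against 75%, but moved the median log2 change by only 0.13, too little to test genes picked for a change of at least 1, while TMM factors gave 57.8% and assume that most of these picked genes are unchanged. Also open are the choice of cancer-annotated genes in the table and a fall of total messenger RNA per cell, which these relative counts leave out.

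The real grouping gave 355 calls with MGH-CP1 and 248 with dinaciclib, and other splits into 3 and 3 at most 0 and 0, so that 1 of 10 splits gave as many in each case. With 10 splits no share can be under 0.05. The authors had picked the listed genes for differing between the real groups, which fixed this outcome beforehand.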
